A study of Mus musculus with 6 samples.

How the data were processed

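The data are 6 lists of ATAC-seq peaks from limb bud mesenchyme of E14.5 mouse embryos, 3 from cells that express bovine Creb5 (iCreb5) and 3 from cells that express tdTomato (iTdtomato). Per the labels' protocols, 50000 sorted cells per library were lysed, the nuclei treated with Tn5 transposase and the DNA amplified with a barcode per sample. All libraries carry the same preparation date, so no batch could be set apart. Groups and replicate letters were taken from the labels. The design text names 3 independent litters; the labels do not say which library came from which litter.

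FastQC, Bowtie2 and MACS2 were used on mm10, per the submitters' processing notes, which give no versions or parameters. Whether reads were shifted for the transposase, filtered by fragment length or freed of duplicates is not given in the sources used here, nor is the meaning of a suffix in the list names. Each deposited list holds the peaks of 1 library, so replicates were not pooled. The deposited score is 10 times the -log10 q of a peak, cut to a whole number, and was not used. The deposited fold of a peak is the ratio of summit pileup plus 1 over background plus 1, with 1 background value per library, as found from the values. The deposited -log10 p-value and -log10 q-value are those of the authors' peak caller at the summit, and every peak has a q-value under 0.05. The last deposited column is the summit position within the peak. These values are the authors' own and were used only to describe, rank or filter peaks within a list.

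Whole-number summit pileups were recovered from the fold, within a tolerance of 0.01, for 100% of peaks in every library; the Poisson p-value of that pileup gave the deposited p-value for 99.98% to 99.99% of peaks. The smallest pileup that made a peak was 4 fragments in iCreb5 replicate a and 3 in the other libraries. The background was 0.250 ± 0.0762 fragments in iCreb5 and 0.266 ± 0.0300 in iTdtomato (SD, n = 3 each; exact permutation p = 0.7). It stands in for depth, which is otherwise unknown here: iCreb5 replicate a had the highest background, 0.337, and the fewest peaks. A region with no peak can hold fragments below that smallest pileup, so absence of a peak is no measure of closed chromatin. Any 2 lists shared 0.0750% to 0.121% of their exact intervals, so none was a copy of another.

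Peaks on chromosomes 1 to 19 and X that share at least 1 bp were merged into regions, and a library holds a region if it has a peak there. Regions in 3 of 3 libraries of 1 group and 0 of 3 of the other were counted. Their expected number came from a log-linear model with 1 term per library, fitted to the 20 sets of regions held by exactly 3 libraries. Overlap is the Jaccard index over regions. Values per library were compared with two-sided exact permutation tests over 20 assignments of the labels, whose smallest p is 0.1. Shares of regions were compared with Fisher's exact test, adjusted over 9 tests by the Benjamini-Hochberg method, and gene density with a permutation test of 100000 resamples.

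Gene positions came from a RefSeq table of GRCm38.p6, whose coordinates are those of mm10. It gives gene spans without strand, exons or sequence. The planned classes of promoter, exon and intron were therefore replaced by gene end (within 1 kb of either end of a protein-coding gene), gene body and intergenic. The planned motif search and the planned separation of Creb5 exons were not run, since no genome sequence or exon table was used here. Regions were assigned to each protein-coding gene that holds them, otherwise to the nearest gene end within 100 kb. For 12 gene lists with 198 genes, the share of regions in each set was compared with that of 10000 random lists matched on regions per gene, two-sided, with adjustment over 24 comparisons. The lists, groups, tests, named-gene rule and most alternatives were fixed before the data were examined.

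The text names Creb5, Prrx1 and the other joint genes; up to 4 genes of each other list whose iCreb5-only and iTdtomato-only counts differ by at least 2; the 12 genes with the largest difference in each direction; and the 8 regions of each set with the highest minimum -log10 q, 1 of which is not reported here. Ties for the 12 genes went to the gene with the larger share of its regions in the set. Genes named for their limma values were chosen after those values were seen.

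The number of regions per gene and library was tested with limma, a choice made after seeing the data: log2 of the number scaled to equal totals plus 0.5, for the 4623 genes with a mean of at least 8 regions, with a trended variance and Benjamini-Hochberg adjustment. A fold on this scale understates changes of genes with few regions. Alternatives were stricter or equal-length lists, other overlap rules, other gene distances, each library left out, and the replicate letters as a block. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.

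The counts of group-only regions, the gene list test and the limma test were tried on simulated data; the overlap, place and gene-density tests were not. With pileups drawn for the 322072 regions and no difference between groups, 257 iCreb5-only and 4614 iTdtomato-only regions arose, 1.03 and 1.01 times the expectation, and the mixed sets lay at 0.939 to 1.04. The data held 1144 and 3494, so the simulated counts differ from the real ones and do not calibrate the ratios seen there. Of 50 shared regions closed in 1 group, 96.0% were recovered; of 50 lowered 8-fold, 64.0%, 4-fold, 26.0%, and 2-fold, 2.00%. So the rule missed most changes of 4-fold or less. Of 100 lists of 22 genes drawn from 19008, 2.00% had an unadjusted permutation p under 0.05 for iCreb5-only regions. With such regions at 2, 4 and 8 times the overall rate, 15.0%, 58.0% and 97.0% of the lists did. These genes were drawn without regard to their number of regions. All genes together had 291653 assigned regions and the 22 joint genes 1024, so these shares need not hold for the joint list. For the limma step, 50 genes of each size were changed among 4623: 2.00%, 30.0%, 74.0% and 76.0% of those with a log2 change of 0.5, 1, 1.5 and 2 were recovered, with 2 false calls.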

Results

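Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA and tags the cut ends for sequencing, in mesenchymal cells sorted from E14.5 mouse limb buds. Prrx1-Cre, a recombinase made in early limb mesenchyme, switched on 1 of 2 alleles at the Rosa26 locus. In the iCreb5 group this was bovine Creb5 followed by GFP, and in the iTdtomato group the red fluorescent protein tdTomato, which served as the control. Creb5 is a basic leucine zipper transcription factor of the CREB/ATF family. The series asks whether Creb5 acts on its own gene and on the genes of the joint interzone, the cell layer that forms where synovial joints will lie. Each group had 3 libraries of 50000 cells, from 3 independent litters in all, and each library had its own peak list on mm10. The lists held 118126, 125316 and 133309 peaks in iCreb5 replicates a, b and c, and 144710, 174697 and 180078 in the iTdtomato replicates. Peaks that shared at least 1 bp were merged into 322072 regions on chromosomes 1 to 19 and X. Of these, 55578 (17.3%) held a peak in all 6 libraries and 173477 (53.9%) in 1 library alone.

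Regions with a peak in 1 group alone made up a small part of the map. A peak in all 3 iCreb5 libraries and in no iTdtomato library was found in 1144 regions, and the reverse in 3494 regions. These are called iCreb5-only and iTdtomato-only regions. In both sets the median of a region's smallest pileup was 4 fragments, close to the 3 or 4 that a peak needed. Fewer fragments can lie in the other group's libraries, so these regions are not shown to be closed there. Strong iCreb5-only regions lay within Igf2bp3, which encodes an RNA-binding protein (chromosome 6, 49145021 to 49145317; summit pileups of 18, 13 and 15 fragments), and at an end of Serping1, the C1 inhibitor gene (chromosome 2, 84765873 to 84766204; 17, 11 and 17 fragments). Next came regions within Atp10b (chromosome 11, 43182460 to 43182677) and Ptprd (chromosome 4, 76797043 to 76797365), and intergenic regions 35.4 kb from Mpped2 (chromosome 2, 106657459 to 106657823), 57.0 kb from Slc30a5 (chromosome 13, 100890444 to 100890776) and on chromosome 15 (56425921 to 56426249).

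The strongest iTdtomato-only regions were narrow. On chromosome 17 a region of 68 bp (93680668 to 93680735) with no protein-coding gene end within 100 kb had summit pileups of 29, 29 and 27 fragments. A region of 123 bp lay 4.95 kb from Dnajc27 (chromosome 12, 4077496 to 4077618; 30, 18 and 19 fragments), and 1 of 53 bp within Cep295 (chromosome 9, 15321769 to 15321821; 13, 16 and 14 fragments). The others on the list of 8 had smaller pileups and lay 10.8 kb from Acvr1b, a receptor gene of the activin pathway (chromosome 15, 101163063 to 101163225), 29.2 kb from the homeobox gene Barx2 (chromosome 9, 31942482 to 31942611), 1.92 kb from Tuft1 (chromosome 3, 94610559 to 94610833), and on chromosomes 7 (69101913 to 69101990) and 14 (100453310 to 100453450) with no gene end within 100 kb.

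Both sets were larger than the libraries' own rates predict. From the rate of each library among regions held by exactly 3 libraries, 391 iCreb5-only and 2475 iTdtomato-only regions were expected, so the observed numbers were 2.93 and 1.41 times the expectation. The 18 sets that mix the groups ranged from 0.736 to 1.2 times theirs. Data simulated without a group difference gave 1.03 and 1.01 times the expectation. They held 4614 iTdtomato-only regions, more than the 3494 observed, so they do not calibrate these ratios. No p-value was given to single regions, since 3 libraries against 3 cannot give an exact p below 0.1. The balance between the sets depended on list length: with the 118126 strongest peaks of each library there were 1937 iCreb5-only and 1602 iTdtomato-only regions, 2.08 and 1.83 times the expectation. With any 1 of the 6 libraries left out, which loosens the rule, the counts were 1753 to 3012 and 5473 to 10657.

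**Figure D1:**
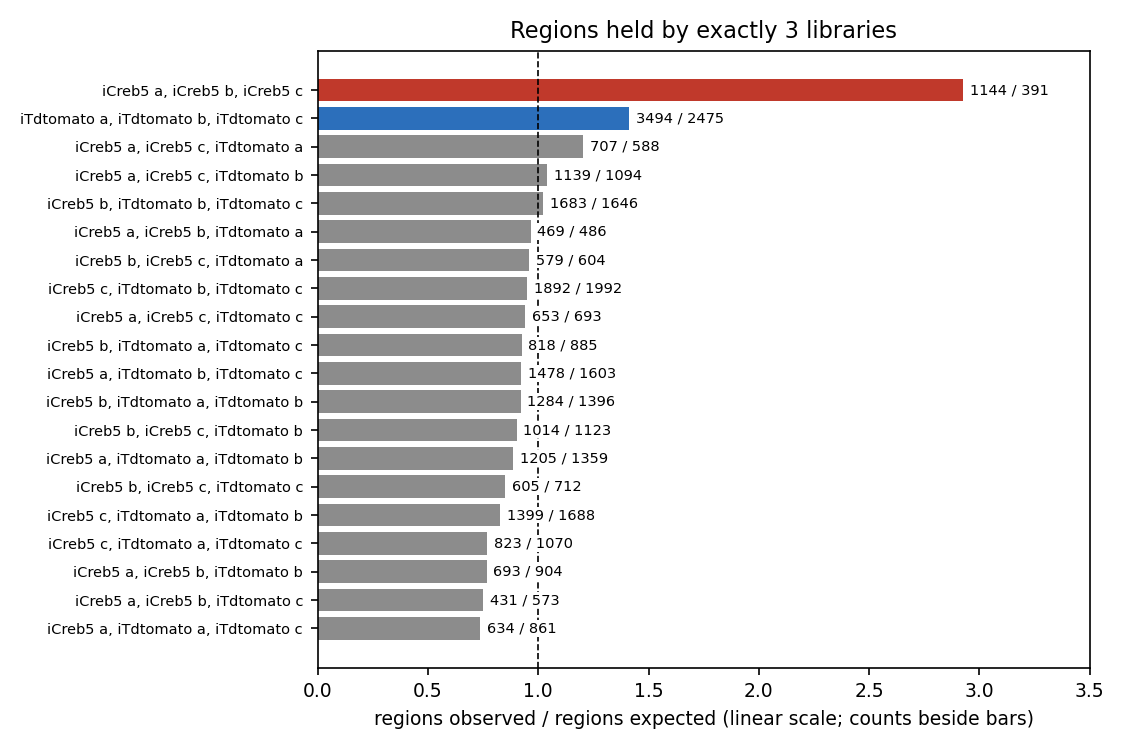
Regions held by exactly 3 of the 6 libraries, for each of the 20 possible sets. Bars give the number observed over the number expected from the rates of the libraries, with both numbers beside each bar; the set of 3 iCreb5 libraries (red) stands at 2.93, the set of 3 iTdtomato libraries (blue) at 1.41 and the 18 mixed sets (grey) at 0.736 to 1.2.

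Around Creb5 itself the 2 groups shared their main open regions. Creb5 (NCBI gene 231991) spans chromosome 6 from 53287226 to 53700364. Within the gene and 100 kb on either side lay 195 regions, of which 24 were open in all 6 libraries, 2 were iCreb5-only, 4 were iTdtomato-only and 165 had another pattern. The shared regions included the lower-coordinate end of the gene (53286952 to 53287482; pileups of 17, 12 and 15 in iCreb5 and 14, 16 and 12 in iTdtomato) and strong regions inside it, such as 53572989 to 53573495 (24, 20 and 20 against 21, 32 and 20) and 53615545 to 53616306 (23, 14 and 18 against 17, 23 and 19). In 2 of the 24 every iCreb5 pileup was above every iTdtomato pileup, at 53337080 to 53337843 (19, 12 and 15 against 8, 11 and 10) and 53612303 to 53612618 (6, 5 and 6 against 3, 4 and 4), and in 1 it was the reverse, at 53654313 to 53654842 (13, 14 and 6 against 15, 20 and 15). Among all 55578 shared regions 3.10% and 3.09% were so; pileups were not scaled for depth, and these regions were chosen after their values were seen. The iCreb5-only regions were 1 inside the gene (53306845 to 53307089; 9, 3 and 4 fragments) and 1 beyond it, nearer to Tril (53781314 to 53781404; 7, 3 and 5 fragments). All 4 iTdtomato-only regions lay inside Creb5, the strongest at 53381302 to 53381545 (8, 7 and 10 fragments), followed by 53618133 to 53618450, 53646195 to 53646369 and 53449946 to 53450121, none of them above 6 fragments.

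Of the 184 regions assigned to Creb5, the iCreb5 libraries held 62.0 ± 15.7 (SD, n = 3; 51, 55 and 80) and the iTdtomato libraries 78.7 ± 8.14 (n = 3; 73, 88 and 75). After scaling to equal totals the difference was 0.05 on the log2 scale (SE 0.12, limma adjusted p = 0.900). It was -0.10 (SE 0.13) without iCreb5 replicate c and -0.03 (SE 0.14) without iTdtomato replicate c. Replicate c of iCreb5 alone held 12 regions of Creb5 between 53688449 and 53697678, up to 816 bp wide, chosen here after they were seen; no other library held more than 4 regions of its own within any 10 kb of the gene. The count of iCreb5-only minus iTdtomato-only regions of Creb5 was -3; it was 1 with lists of equal length, 0 without iCreb5 replicate b or with -log10 q of at least 5, -5 for at least 2 of 3 libraries against 0 of 3, -6 without iTdtomato replicate a and -7 without iTdtomato replicate c. Exons and introns were not told apart here, so fragments of the bovine transgene that align to mouse exons were not separated.

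**Figure D2:**
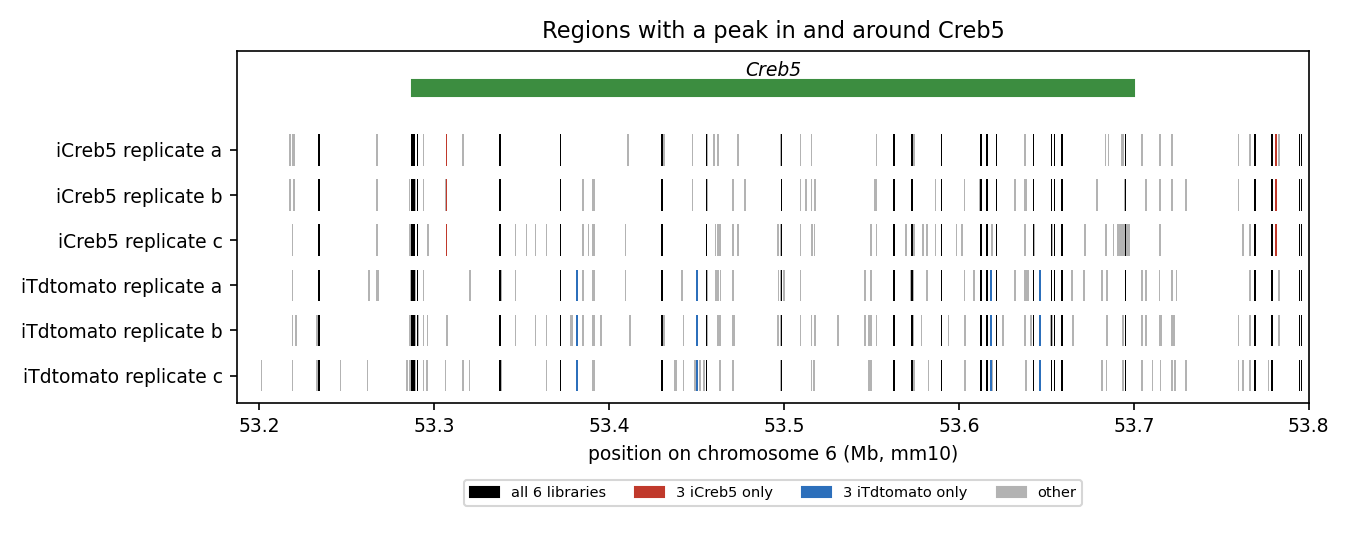
Regions with a peak in and within 100 kb of Creb5, by position on chromosome 6 (Mb, mm10), with 1 line per library and the gene as a green bar, narrow regions being drawn wider so that they can be seen. Of the 195 regions, 24 had a peak in all 6 libraries (black), 2 in the 3 iCreb5 libraries alone (red) and 4 in the 3 iTdtomato libraries alone (blue).

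Genes of the joint interzone and articular list had open regions in both groups. All 22 genes of this list had at least 1 region shared by the 6 libraries. So did all 20 chondrocyte, 26 signalling, 11 endothelial and 6 neural crest or Schwann genes, so this measure is not particular to joint genes. Among the joint genes were Gdf5 (3 shared regions) and Gdf6 (8), which encode joint-inducing growth factors, Erg (17), Trps1 (15), Has2 (12), Sfrp2 (9), Enpp2 (8), Wnt9a (7), Osr2 (5), Wnt4 (4) and Prg4 (4), the lubricin gene. Per 1000 regions of all genes, the list held 3.5 ± 0.291 in iCreb5 and 3.38 ± 0.178 in iTdtomato (SD, n = 3 each; exact permutation p = 0.7). Of its 1024 regions, 4 (0.391%) were iCreb5-only, 1 each at Creb5, Enpp2, Erg and Trps1, against a median of 0.335% in 10000 random gene lists matched on regions per gene (permutation p = 0.811, adjusted p = 1). Another 12 (1.17%) were iTdtomato-only, 4 of them at Creb5 and 1 each at Barx1, Cd44, Enpp2, Gdf5, Osr1, Sfrp2, Wnt4 and Wnt9a, against 1.22% in random lists (permutation p = 0.889, adjusted p = 1).

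A looser rule gave another picture for the joint list. With regions in at least 2 of 3 iCreb5 and 0 of 3 iTdtomato libraries, 36 of the 1024 regions (3.52%) counted, spread over 16 of the 22 genes, against 1.75% in random lists (permutation p = 0.0010, adjusted p = 0.0240 over 24 comparisons). Creb5 held 9 of them, Enpp2, which encodes autotaxin, 4 of its 35 regions, Gdf6 and Erg 3 each, and Wnt16 2 of its 10 regions. Under the reverse rule 66 regions (6.45%) counted, 14 of them at Creb5, against 6.22% in random lists (permutation p = 0.787). The random lists vary the genes and not the libraries, so this p does not cover differences between single libraries. The excess depended on iCreb5 replicate c, which held 3.84 joint regions per 1000, more than any other library. Leaving out an iCreb5 library asks for both of the others, which lowers the count by construction. Without replicate c 9 regions (0.879%) counted against 0.693% in random lists (permutation p = 0.531), without replicate a 16 (1.56% against 0.826%, permutation p = 0.0390) and without replicate b 19 (1.86% against 0.908%, permutation p = 0.0114).

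By the number of regions per gene and library, 19 joint genes could be tested with limma, of which 10 were higher and 9 lower in iCreb5; 0 passed after adjustment over all genes, 0 adjusted over the list alone and 1 had an unadjusted p under 0.05. Gdf6 had the smallest p, at 18 ± 2.65 regions in each group (SD, n = 3) and a log2 difference of 0.41 after scaling (SE 0.16, limma adjusted p = 0.349). Prrx1, whose regulatory sequence drives the Cre, held 20 ± 2.65 and 26.3 ± 2.89 regions (SD, n = 3), a log2 difference of 0.02 after scaling (SE 0.15, limma adjusted p = 0.973).

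**Figure D3:**
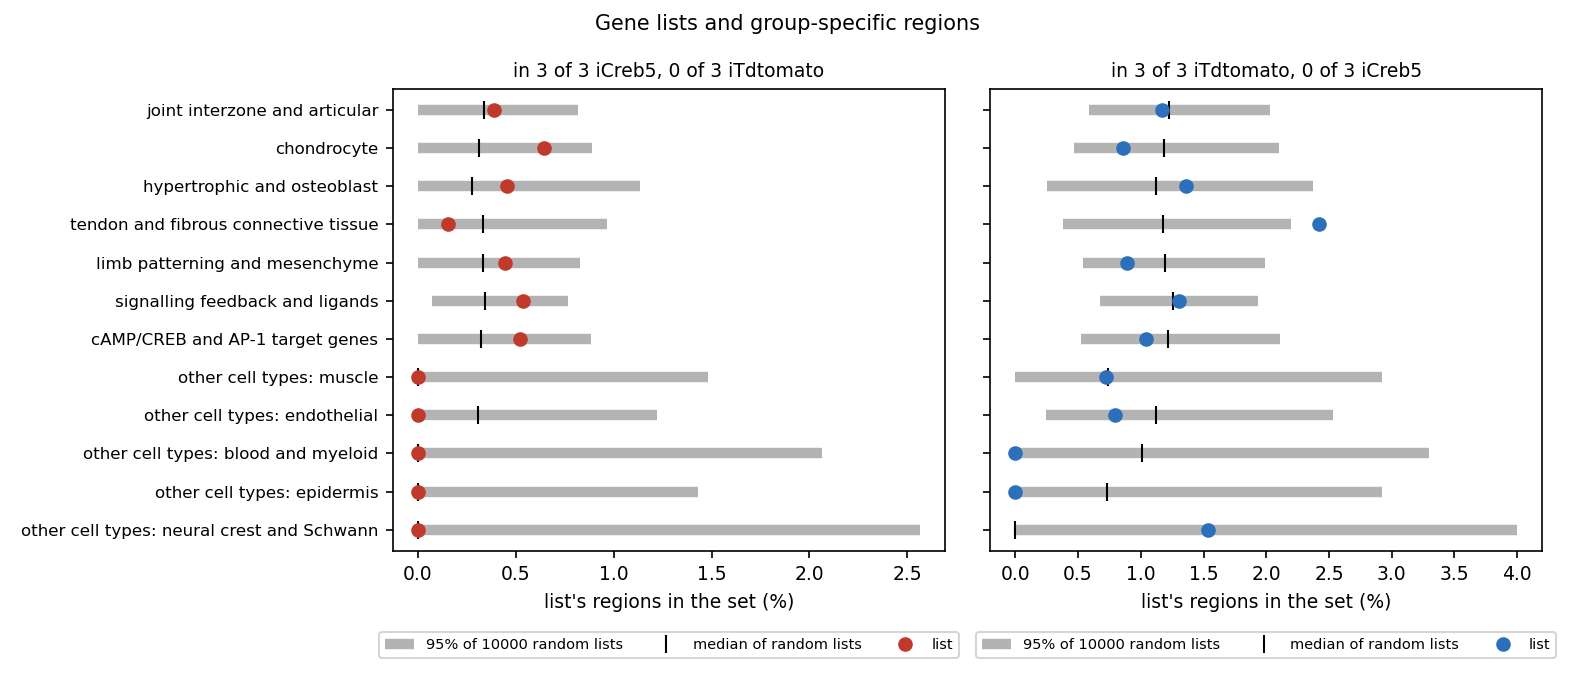
Share of the regions of each gene list that were iCreb5-only (left, red) and iTdtomato-only (right, blue), in percent; grey bars span 95% of 10000 random gene lists matched on regions per gene and black ticks their median. The joint list lies near the median on both sides (0.391% and 1.17%), and the tendon list is the only 1 of 12 above its grey bar, on the right (2.42%).

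Of the other lists, tendon and fibrous connective tissue stood furthest out: 16 of its 660 regions (2.42%) were iTdtomato-only against 1.18% in random lists, with a permutation p of 0.0168 that did not pass adjustment over 24 comparisons (adjusted p = 0.403). They included 5 regions at Tcf7l2, a Wnt effector found in connective tissue fibroblasts, and 2 each at Egr2, Thbs2 and Tnc, the tenascin C gene. This list made up 2.17 ± 0.0770 of every 1000 regions in iCreb5 and 2.37 ± 0.0834 in iTdtomato (SD, n = 3 each; exact permutation p = 0.1, the smallest that 3 against 3 allow). Chondrocyte genes had 6 iCreb5-only (0.644%) and 8 iTdtomato-only regions (0.859%), 2 of the latter at Col2a1, the gene of the main cartilage collagen. Hypertrophic and osteoblast genes had 2 and 6, and limb patterning genes 4 and 8.

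Among signalling genes 7 regions were iCreb5-only and 17 iTdtomato-only. The former included 3 at Ptch1, the hedgehog receptor, and the latter 4 at Bmp7, 3 at Tgfb2 and 2 at Nkd1. Genes that respond to cAMP or AP-1 had 5 and 10, the latter with 2 each at Pde4b and Ppargc1a. None of these lists passed adjustment in either direction (adjusted p = 1 throughout). Markers of other cell types had 0 iCreb5-only regions in muscle (138 regions), endothelium (252), blood (90), epidermis (138) and neural crest or Schwann cells (65), and 1, 2, 0, 0 and 1 iTdtomato-only regions. Of the 24 comparisons with random lists, 0 passed adjustment and 1 had an unadjusted permutation p under 0.05.

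Within the lists, regions per gene gave single genes a limma p that passed when adjusted over the list alone, though 0 passed over all genes. These genes were chosen after their values were seen. Fos and Fosb, immediate early genes of AP-1, had log2 differences of 0.40 (SE 0.14) and 0.60 (SE 0.20) towards iCreb5 (limma adjusted p = 0.0489 for both, adjusted over the list alone). Unscaled, the libraries held 31.3 and 31.7 regions of Fos and 13 and 11.3 of Fosb (means of iCreb5 and iTdtomato), so for Fos the direction came from scaling to equal totals. In the same list Nr4a1, an orphan nuclear receptor gene, stood at -0.61 (SE 0.22; 0.0511). Egr2, from the tendon list, stood at -0.63 (SE 0.19; 0.0336), with 9.0 ± 1.0 regions in iCreb5 and 19 ± 3.00 in iTdtomato (SD, n = 3). Pecam1, an endothelial marker, stood at -0.81 (SE 0.27; 0.0289, 5 genes tested) and Fcgr3, a myeloid marker, at 0.78 (SE 0.24; 0.00660, 2 genes tested).

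Over all genes, those with the most iCreb5-only minus iTdtomato-only regions were Nkain3, a gene of 670 kb on chromosome 4 (5 regions), and Cmss1 on chromosome 16 (5 regions). The latter overlaps Filip1l (3 regions), so that regions in the shared stretch count for both. Agap1 had 4 against 1, and Gas2, Baz2b, Ptch1, Mpped2, Bcl2, an inhibitor of cell death, and Ptprg had 3 each and 0 in the other direction. Npepps and the keratin gene Krt17 had 2 each, and were listed because ties went to genes with the larger share of iCreb5-only regions. Krt17 had 3 regions in all, of which the iCreb5 libraries held 2, 3 and 2 and each iTdtomato library 0. That pattern follows in part from the rule that picked it. At the other extreme stood Gpc3, a glypican gene on chromosome X that limits growth, with 8 iTdtomato-only regions among 41. It held 9.67 ± 2.31 regions in iCreb5 and 21.3 ± 2.31 in iTdtomato (SD, n = 3). Ctdspl, Phactr2 and Dnm3 had 6 iTdtomato-only regions each, and Srgap1, Arhgef3, Tcf7l2, Mast4 and Wwox 5 each. Cd2ap, Lrrc32 and Vac14 had 4 each, and all of these genes had 0 iCreb5-only regions. Genes with many regions can reach such counts more easily: Wwox had 203 regions in all, Dnm3 162, Mast4 153 and Agap1 152.

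In the limma test of regions per gene, 0 of 4623 genes passed an adjusted p of 0.05 in either direction, 4 passed 0.1 and 506 had an unadjusted p under 0.05. Nkain3 was at 0.83 (SE 0.16) and Atp10b, a flippase gene, at 1.11 (SE 0.21), both with an adjusted p of 0.0553. Cdh6, a cadherin gene, was at 0.82 (SE 0.17) and Vav2 at -0.84 (SE 0.17), both with an adjusted p of 0.0765. Atp10b, Cdh6 and Vav2 were chosen after their values were seen. Of the genes named above, Gas2 was at 0.70 (SE 0.19), Cmss1 at 0.51 (SE 0.13), Gpc3 at -0.72 (SE 0.20) and Lrrc32 at -0.83 (SE 0.21). Smaller differences were seen for Tcf7l2 (-0.02, SE 0.12), Mast4 (-0.09, SE 0.12), Agap1 (0.11, SE 0.11) and Ptprg (0.12, SE 0.11). None of these genes had a limma adjusted p below 0.1. Without iTdtomato replicate a 18 genes passed 0.05, and with lists of equal length 7, all of them higher in iCreb5. With the replicate letters as a block 38 passed, 15 higher and 23 lower in iCreb5, but the labels do not say what the letters mark.

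The iCreb5-only regions lay away from gene ends and in gene-poorer DNA. Only 57 of the 1144 (4.98%) touched the 1 kb around an end of a protein-coding gene, against 337 of the 3494 iTdtomato-only regions (9.65%; odds ratio 0.491, Fisher's exact test, adjusted p = 4.34e-07) and 28.4% of the regions shared by 6 libraries. Gene bodies held 48.2% of iCreb5-only and 48.5% of iTdtomato-only regions, and 46.9% and 41.8% were intergenic (odds ratio 1.23, adjusted p = 0.00347). Within 500 kb of an iCreb5-only region lay 9.64 protein-coding genes on average (SE 0.280 over regions), against 12.4 (SE 0.183) for iTdtomato-only and 14.8 for shared regions. The difference of -2.79 genes had a permutation p over regions of 2.00e-05, the smallest possible with 100000 resamples. The 18 sets that mix the groups had 8.26% to 15.3% at gene ends and 10.9 to 13.8 genes, so both values of the iCreb5-only set lay outside their range. Regions are not independent replicates. The intergenic difference did not hold with -log10 q of at least 5 (odds ratio 1.07, Fisher's exact test, p = 0.507). Nor did it hold with lists of equal length (1.12, Fisher's exact test, p = 0.103). Gene density is given for the full lists alone, so whether its difference holds under those settings is not known.

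**Figure D4:**
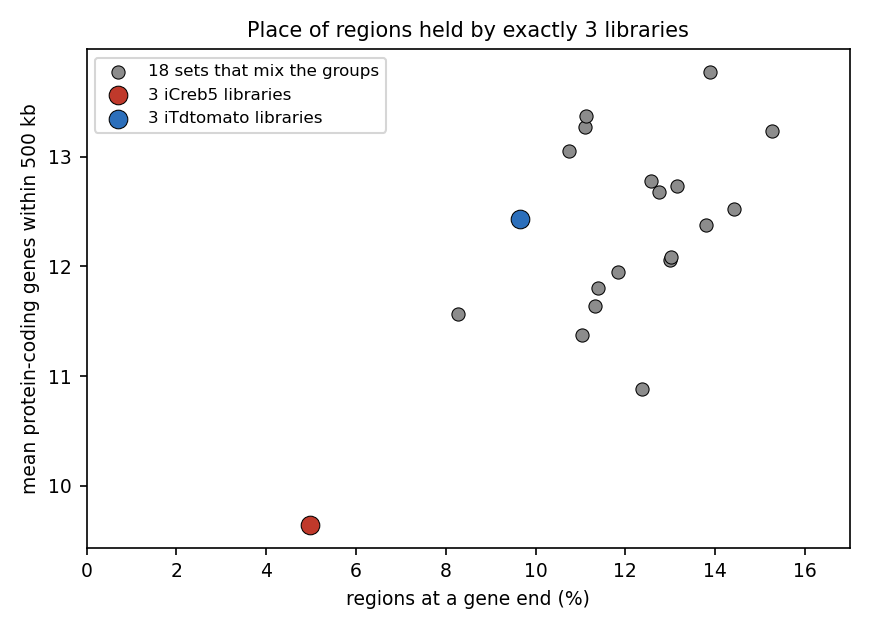
Share of regions at a gene end (percent) against the mean number of protein-coding genes within 500 kb, for the 20 sets of regions held by exactly 3 libraries. The set of 3 iCreb5 libraries (red) lies at 4.98% and 9.64 genes, the set of 3 iTdtomato libraries (blue) at 9.65% and 12.4, and the 18 mixed sets (grey) at 8.26% to 15.3% and 10.9 to 13.8.

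The iCreb5 libraries had fewer peaks in total. They held 125584 ± 7595 peaks and the iTdtomato libraries 166495 ± 19057 (SD, n = 3 each), 24.6% fewer, and covered 21.7 ± 1.44 against 27.6 ± 3.36 Mb. Every iCreb5 library lay below every iTdtomato library in both, with an exact permutation p of 0.1, the smallest that 3 against 3 allow. With summit pileups of at least 6 fragments, the means were 75194 and 78501 (exact permutation p = 0.7), but the iCreb5 libraries differed among themselves. Replicate a held 92542 such peaks, more than any iTdtomato library, and replicates b and c held 63417 and 69624, fewer than each of the 3. Without iCreb5 replicate a the difference at 6 fragments was -11980.5 peaks (exact permutation p = 0.2), and without replicate b it was 2582 (exact permutation p = 1). With -log10 q of at least 5 the means differed by -3458 (exact permutation p = 0.8). Median peak width was 121 ± 6.03 and 111 ± 11.4 bp (exact permutation p = 0.3).

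**Figure D5:**
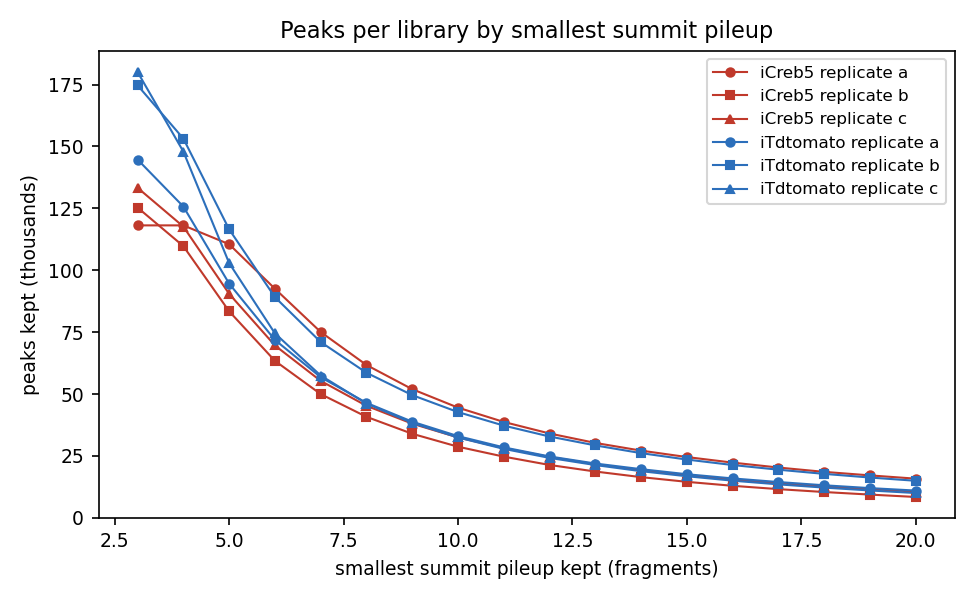
Number of peaks kept in each library as the smallest summit pileup (fragments) is raised, with 1 line per library, iCreb5 in red and iTdtomato in blue. All iTdtomato lines start above the iCreb5 lines (144710 to 180078 against 118126 to 133309 peaks), and from 5 fragments on iCreb5 replicate a lies among or above the iTdtomato lines, while replicates b and c stay below them up to 9 fragments.

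The iCreb5 libraries were also more alike. Pairs of them shared 0.503 ± 0.0216 of their joined regions (Jaccard index, SD over 3 pairs), pairs of iTdtomato libraries 0.412 ± 0.0222, and pairs across the groups 0.426 ± 0.0315 (9 pairs). By this index, pairs of iTdtomato libraries were thus no more alike than pairs across the groups. iTdtomato replicate a overlapped iCreb5 replicates a, b and c (0.477, 0.449 and 0.451) more than iTdtomato replicates b and c (0.437 and 0.395). The index also depends on list length, and iTdtomato replicates b and c had the longest lists (174697 and 180078 peaks). iCreb5 replicate a likewise overlapped them less (0.440 and 0.400) than iTdtomato replicate a (0.477). With lists of equal length the iCreb5 and iTdtomato pairs are not given apart. Likeness among the iTdtomato libraries is therefore left open. Over both groups, pairs within a group exceeded pairs across groups by 0.0312 (exact permutation p = 0.1, the smallest possible with 10 splits). With the full lists the excess came from the iCreb5 pairs. That excess was 0.0202 with lists of equal length, 0.0167 with -log10 q of at least 5 (exact permutation p = 0.1 for both) and 0.0147 with at least 10 (exact permutation p = 0.2). It was 0.00818 to 0.00910 without any 1 of the iCreb5 libraries (exact permutation p = 0.3) and 0.0422 to 0.0682 without any 1 of the iTdtomato libraries.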

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

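Chosen after seeing the data were the strong-region rule, the pileup minimum of 4 fragments, coverage of the merged region, the observed-over-expected ratios, the gene-end odds ratios, all limma tests, the checks of the joint list under at least 2 of 3 libraries and the values for high pileups with 1 library left out; the other alternatives were planned. Counts of iCreb5-only and iTdtomato-only regions (1144 and 3494) moved with the setting. They were 947 and 891 with -log10 q of at least 5, 689 and 233 with at least 10, 1937 and 1602 with lists of equal length, and 5679 and 18202 for at least 2 of 3 libraries against 0 of 3. For regions with -log10 q of at least 5 in 3 of 3 libraries and no peak in the other group they were 126 and 121. Leaving out 1 library, which loosens the rule by its construction, gave 1753 to 3012 and 5473 to 10657. The counts stayed within 1.5 times with summits widened by 100 bp (1299 and 3829), autosomes alone (1127 and 3418), a pileup of at least 4 (1171 and 2933) and 50% of the merged region covered (1246 and 3609). Asking for 50% of the shortest peak moves nothing by construction. Of the alternatives above, the observed-over-expected ratios were computed for equal lists, a pileup of at least 4 and -log10 q of at least 5 alone. There they lay above the mixed sets, at 2.08 to 2.90 and 1.48 to 1.83.

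The lower share of gene ends among iCreb5-only regions held under 10 of 10 alternatives (odds ratios 0.519 to 0.762). The share itself, 4.98%, rose to 7.49% without iCreb5 replicate c and to 8.15% for at least 2 of 3 libraries. The iTdtomato-only shares were 10% and 10.4% there. The intergenic odds ratio of 1.23 lost its threshold with -log10 q of at least 5 (1.07) and with equal lists (1.12); the cause was not tested. The net count at Creb5, -3, turned to 1 with equal lists, was 0 with -log10 q of at least 5, -5 for at least 2 of 3 libraries, and -7 to 0 with 1 library left out; the cause was not tested. No gene list passed adjustment except under at least 2 of 3 libraries, where 1 did, the joint list (3.52%, adjusted p = 0.0240); over all 264 list comparisons under alternatives this was the smallest adjusted p. Under that rule the joint share had a permutation p of 0.0290 with equal lists, 0.0166 with pileups of at least 4, 0.0992 with -log10 q of at least 5 and 0.00560 without Creb5, and 0.00500 to 0.531 with 1 library left out. For limma, 7 genes passed with equal lists, and 0 to 18 with 1 library left out, 18 of them without iTdtomato replicate a; 0 passed with -log10 q of at least 5, a mean of at least 4 regions or 1 added.

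No pairing by replicate letter was seen: libraries with the same letter had correlations of -0.00785, -0.00346 and -0.00987 across regions, and none correlated best with its own letter. With 53.9% of regions held by 1 library alone, such correlations can miss a shared litter, so a pairing is not excluded. The difference in peaks per library, -40911, was -3458 with -log10 q of at least 5 (exact permutation p = 0.8). With the letters as a block it stayed the same (-40911, exact sign-flip p = 0.25, the smallest possible). Within a letter, 33536 regions on average were in the iCreb5 library alone and 74393 in the iTdtomato library alone (exact sign-flip p = 0.25), and 38 genes passed in limma, 15 higher and 23 lower in iCreb5; the cause was not tested. Equal lists fix the number of peaks, so they give no value for it, and the motif search was not run. Depth limits all counts: a region needs 3 fragments, or 4 in iCreb5 replicate a, to be seen.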

Other observations

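Chosen after the results were seen were the tests of the splits, of chromosome 6, of peak widths, of the joint list under other splits and of single chromosomes, and the genes named here; for those of gene density, list length and smallest pileup, what each explanation predicts was written before its result was seen, although the smallest pileup of 4 was itself an alternative added after seeing the data.

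Further genes with more open regions in iCreb5, though none past an adjusted limma p of 0.05, included Isl1, a homeobox gene of early hindlimb mesenchyme (log2 0.96, SE 0.23, adjusted p = 0.105), Chl1, a neural adhesion gene (0.80, SE 0.18, adjusted p = 0.105), and Pde8a, a cAMP phosphodiesterase gene (0.75, SE 0.17, adjusted p = 0.105). Genes with fewer included Dlk1, an inhibitor of differentiation (-0.67, SE 0.15, adjusted p = 0.105), Acvrl1, a TGF-beta family receptor gene of endothelium (-1.03, SE 0.25, adjusted p = 0.105), Tnfaip3, which limits NF-kappaB signalling (-0.84, SE 0.20, adjusted p = 0.105), and the mechanosensitive channel gene Piezo1 (-0.66, SE 0.16, adjusted p = 0.105). Among limb patterning genes the unadjusted limma p was under 0.05 for Hand2 (0.49, SE 0.18; unscaled means of 21.3 and 20.3 regions), Meis2 (-0.53, SE 0.17) and Alx4 (-0.49, SE 0.23). In signalling it was so for Dusp6 (0.35, SE 0.16; unscaled means of 21.3 regions in iCreb5 and 22.7 in iTdtomato), Hhip (0.46, SE 0.19; 15.3 and 15), Bmp5 (-0.52, SE 0.21), Bmp7 (-0.30, SE 0.14), Tgfb2 (-0.34, SE 0.16) and Nkd1 (-0.35, SE 0.15). The real groups gave 506 genes at an unadjusted p under 0.05 and the highest other split 300; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

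By chromosome, iCreb5-only regions were scarcest on chromosome 11, with 43 such regions against 3603 shared ones (odds ratio 0.563, Fisher's exact test, adjusted p = 0.00365 over 40 tests). Chromosome 11 is gene-dense (13.2 genes per Mb), so this was not told apart from the gene-density difference above. The gene-dense chromosomes 7, 17 and 19 had odds ratios of 0.770, 0.835 and 0.755, but so had gene-poor X (0.723), and none of these passed. On chromosome 16 the odds ratio was 1.5 (adjusted p = 0.0902) and on chromosome 6 it was 1.37 (adjusted p = 0.0999). No chromosome passed for iTdtomato-only regions. Chromosome Y, left out of the regions, held 18, 25 and 24 peaks in iCreb5 and 22, 57 and 67 in iTdtomato.

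For the joint list under the rule of at least 2 of 3 libraries against 0 of 3, the share in iCreb5 lay at percentile 99.96 of random lists, and the highest of the 18 sets from other splits at 99.94. That set joins iCreb5 replicate c with iTdtomato replicates a and b, and sets of iCreb5 replicates a and c with iTdtomato replicate a, b or c lay at 99.59, 99.66 and 99.90, those of iCreb5 replicates b and c with them at 98.75, 99.82 and 99.86. Of the 10 splits, 1 gave a p as small, and 10 splits are too few for a share under 0.05.

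Regions held by all libraries of 1 group and none of the other exceeded their expected numbers 2.93 and 1.41 times. Over both sets the ratio was 1.62, against 1.07 for the highest of the other splits; 1 of 10 splits reached it, and 10 splits are too few for a share under 0.05. DNA linked to the Rosa26 alleles on chromosome 6 is argued against as the whole source, since without that chromosome the ratios were 2.91 and 1.41, above the highest mixed set at 1.21, although within 20 Mb of Rosa26 iCreb5-only regions stood at 1.46 times the level of other chromosomes (95% interval 0.986 to 2.17). A general pull of the iCreb5 libraries towards gene-poor DNA was looked for in regions found in 1 library alone. These differed in the same direction, by -0.465 genes within 500 kb (SE 0.0580), where the group-only sets differed by -2.79 (SE 0.335). By gene density some pull was thus seen, smaller than the size set beforehand, with SEs that treat regions as independent. By place the single-library regions went the other way. Gene ends held 9.09% of those in iCreb5 and 8.14% of those in iTdtomato, and 42.2% and 43.1% were intergenic. So a general pull is not settled by these regions. Single-library regions had a median width of 68 bp, against 184 and 181 bp in the group-only sets, so a pull on wider regions is left open. Gene density also does not measure the excess in numbers. Neither an effect of Creb5 nor one of the fluorescent protein used for sorting, which differs with the group, was tested.

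More regions were iTdtomato-only than iCreb5-only, 3.05 times as many. Longer lists of weak peaks in the iTdtomato libraries may account for this. With lists of equal length the ratio was 0.827, but such lists bring the expected numbers close together (931 iCreb5-only and 875 iTdtomato-only). That result was largely fixed by the cut and cannot test the explanation. With the full lists the libraries' rates alone predict 391 and 2475, further apart than the 1144 and 3494 observed. The higher pileup that iCreb5 replicate a needed for a peak is argued against as the whole source. With at least 4 fragments in all libraries the ratio was still 2.50. It fell from 3.05, so a part played by that higher pileup is left open. Whether Creb5 reduces weak accessibility, or depth and library quality shorten the lists, was not tested.

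The 3 strongest iTdtomato-only regions, on chromosomes 17, 12 and 9, were narrower than nearly all peaks of like height. Their widths reached at most percentile 3.39 among peaks of the same library with a pileup within 2 fragments. Sequence of another origin aligned to the mouse genome, such as a part of the tdTomato cassette or a repeat, is a candidate source, consistent with that width. No sequence was used here to test it, and no biological explanation was tested.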
